A study of Mus musculus with 14 samples.

How the data were processed

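RNA was measured in 14 mouse liver samples. There were 13 bulk RNA-seq libraries and 1 single-cell library. Per the labels' protocols, hepatic stellate cells, the vitamin A-storing pericytes of the liver sinusoid, were freed from the perfused liver with enzymes and enriched on a gradient. Quiescent, unplated stellate cells (4 libraries) were further sorted for vitamin A and for TdTom switched on by LratCre in C57BL/6J mice, and whole uninjured liver (3 libraries) came from the same strain. Cultured stellate cells (3 control and 3 UDP-glucose libraries) carry the strain label Balbc, and no sort is described for them. They were plated in 10% fetal bovine serum for 5 h, moved to 0.1% serum, and kept for 24 h with or without 10 µM UDP-glucose. The titles of the treated samples say UDP, and their descriptions UDP-glucose. Bulk libraries were made with a TruSeq RNA kit. The single-cell library came from the digested normal liver of a C57BL/6 mouse, with the Chromium 3' v2 kit and 12 cycles each of cDNA and of library amplification.

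The deposited bulk values are TPM (transcript abundance scaled to a fixed library sum) per gene, in 3 tables that list the same 35197 gene rows: 1 for quiescent cells, 1 for whole liver and 1 for both cultured groups. The submitters' processing notes name, among other tools, bcl2fastq 2.19, kallisto 0.44.0 and Cell Ranger, the last without a version, and the builds GRCm38 and mm10. The names of the bulk tables say that their values come from kallisto. Its use of strand is not given in the sources used here. The deposited single-cell values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode. All 13 bulk value columns were used. TPM sums ran from 998190 to 999797 per library. TPM keeps no read depth, so the depth of the bulk libraries is unknown and no count model was fitted. In each of the 3 tables, 26 rows carried calendar dates in place of gene symbols, with 2 such names used more than once. They held at most 0.319% of TPM and were left out, which left 35171 rows. Of these symbols 34873 were found in the GRCm38 annotation used for positions and overlaps. Because strand use is not stated, named genes of the report with over 10% of exon bases in another gene model are reported with that share.

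Bulk comparisons were fitted with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with moderated variances that follow mean expression, over genes with a mean of at least 1 TPM in the libraries compared. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. An absolute log2 fold change of at least 1 was also required for the comparisons of quiescent cells with liver and of cultured with quiescent cells. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Each comparison used its own libraries. Gene lists (17 for processes and 18 for cell types) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 5 tested members. Camera with an estimated correlation was run beside it. So was fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes. The labels do not say that libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Quiescent cells, whole liver and cultured cells stand in separate tables, and TPM is scaled within each library, so in comparisons across tables the table and the group cannot be told apart.

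The groups, tests, thresholds, gene lists, markers, alternatives and the rule for named genes were fixed before the data were examined. The rule took P2ry14 and every purinergic receptor with at least 1 TPM in either group. It added the 10 largest rises and 10 largest falls among called genes of at least 5 TPM whose groups did not overlap, leaving out predicted models, pseudogenes, immunoglobulin and T cell receptor segments and mitochondrial genes. It also took up to 4 called members of each process list, up to 3 abundant members of each cell type list, and Acta2, Col1a1, Lrat, Timp1 and Des in every comparison. Some genes that the rule took are not reported here.

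In the single-cell library, scanpy 1.11.5 in Python 3.11.15 kept barcodes with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. Counts were log-normalised, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave the clusters. Genes leading a cluster were ranked by fold against all other cells after adding 50 CPM. A cluster was named where at least 3 of a type's fixed markers stood among its 50 leading genes, at least 2 times as many as for the next type, with no other type ahead among its 10 leading genes. Where the first leading gene was itself a marker, it also had to belong to that type. This scoring was set after seeing the data, the markers before. Names are written as "-like" because they were rebuilt from markers. Doublets were called with Scrublet, which marked 4 of 5063 barcodes (0.0790%). A call this low means that the caller did not work, so doublets were in effect not removed. With 1 library there is no test. Shares above 0 have exact Clopper-Pearson 95% intervals, shares of 0 an upper limit of 3 cells of the total, and sums have exact Poisson 95% intervals, and both cover counting error only. Shares were also taken after thinning each cell to 1000 UMIs.

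Both fits were tested on simulated data. With 200 genes changed in simulated libraries like those of the UDP-glucose comparison (12161 genes), 36.4%, 70.1% and 94.0% of genes with log2 changes of 0.5, 1 and 2 were called, and 2.90% of calls were false. In the comparison with liver (12643 genes) the shares were 16.7%, 71.6% and 91.0%, with 4% false calls. In that of cultured with quiescent cells (12537 genes) they were 34.8%, 83.6% and 97.0%, with 6.49% false calls. Simulated calls used the adjusted p alone, without the fold minimum required in both of these comparisons, and so describe a looser rule. Far more than 200 genes were called in the real data there, so these false-call shares do not carry over. In every comparison the genes were simulated independently of each other. The 2.90% therefore cannot be read as the error share of the real UDP-glucose calls. Simulated single cells, drawn from the summed profile of each named class, were assigned to the right class in 100% of 4348 cells. They held no added doublets, no unnamed clusters and no variation within a class beyond counting. This share therefore does not measure how often real cells were named correctly. Alternatives were other pseudocounts, no filter or a filter at 5 TPM, median-of-ratios and quantile scaling, rescaling without the 100 most abundant genes, other variance models, all 13 libraries in 1 fit, no fold minimum, and leaving out each library. For single cells they were other resolutions, filters and depth, and classes set from detected markers alone. The alternatives added after seeing the data left out the 5% of cells with the highest doublet scores and the cells of unnamed clusters.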

Results

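Transcript abundance was measured in bulk in 4 libraries of quiescent, unplated hepatic stellate cells, 3 of whole uninjured liver, 3 of stellate cells cultured for 24 h and 3 of stellate cells cultured for 24 h with 10 µM UDP-glucose. UDP-glucose is a nucleotide sugar, used inside cells to build glycogen and glycans, that activates the receptor P2Y14 when it is released. A further library profiled single cells of a digested normal liver. The series asks whether P2Y14, encoded by P2ry14, ties the death of hepatocytes to the activation of stellate cells, the main source of scar matrix in the injured liver. Values are mean ± SD. Genes with at least 1 TPM numbered 12225 ± 45.5 in quiescent cells (n = 4), 10242 ± 266 in liver (n = 3), 12196 ± 208 in control cultures (n = 3) and 12100.0 ± 49.7 in UDP-glucose cultures (n = 3). Mitochondrial transcripts took 5.11% ± 0.372, 19.98% ± 2.10, 3.11% ± 0.106 and 3.61% ± 0.802 of TPM in the same order. In liver the 10 most abundant genes held 31.6% ± 4.21 of TPM, and the Mup genes, which encode urinary proteins made by hepatocytes, held 22.2% ± 9.30. Within groups, log2 values of library pairs correlated at 0.981 to 0.991 across 12931 genes, which are not independent replicates. The bulk read depth is unknown.

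Quiescent stellate cells were compared with whole liver to see which transcripts, P2ry14 among them, were concentrated in this cell type. P2ry14 was 132 ± 4.78 TPM in quiescent stellate cells (n = 4) and 0.341 ± 0.166 TPM in liver (n = 3), a log2 fold change of 6.63 (SE 0.12, limma adjusted p = 3.28e-12). The stellate cell libraries held 133, 126, 129 and 137 TPM and the liver libraries 0.159, 0.382 and 0.483 TPM. Lrat, which esterifies retinol for storage, was 1089 ± 205 against 1.05 ± 0.388 TPM (log2 9.05, adjusted p = 5.26e-12), and Des, an intermediate filament of stellate cells, was 235 ± 18.0 against 0.943 ± 0.334 TPM (log2 6.93, adjusted p = 5.67e-12). Transcripts of hepatocyte secreted proteins lay far lower in stellate cells. Ttr, the thyroid hormone carrier, was 0.539 ± 0.417 against 5592 ± 1267 TPM, and Apoa2, an apolipoprotein, 2.61 ± 1.05 against 17807 ± 3929 TPM. P2ry14 (ENSMUSG00000036381.13) lies on the minus strand of chromosome 3, from 59113855 to 59153618 in GRCm38. It sits inside the gene Med12l on the plus strand (59005825 to 59318682), and 0% of its exon bases overlap exons of another gene.

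**Figure D1:**
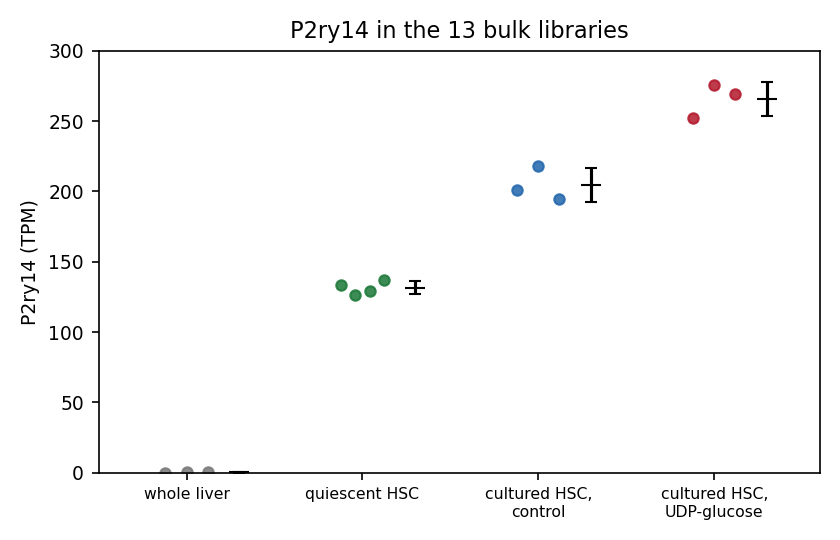
P2ry14 in TPM (vertical axis) in each of the 13 bulk libraries, by group. Dots are libraries and bars are the mean ± SD. The 3 liver libraries lie between 0.159 and 0.483 TPM, the 4 quiescent libraries between 126 and 137 TPM, the 3 control cultures between 194 and 218 TPM and the 3 UDP-glucose cultures between 252 and 276 TPM.

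Of 8 purinergic receptors tested against liver, 6 rose and 1 fell, and the counts were the same adjusted over the list alone (4 and 2 after median-of-ratios rescaling). Adora2a, an adenosine receptor, was 96.8 ± 12.9 against 0.428 ± 0.150 TPM (log2 6.09), and P2ry1, an ADP receptor, was 20.6 ± 2.02 against 1.25 ± 0.350 TPM (log2 3.27). The ATP-gated channel P2rx1 was 5.34 ± 0.542 against 0.0515 ± 0.0892 TPM (log2 2.59), and the adenosine receptor Adora1 fell from 3.22 ± 0.878 in liver to 0.00767 ± 0.0153 TPM (log2 −2.05). Of the exon bases of P2ry1 and Adora1, 23.1% and 20.1% overlap another gene model. P2rx4 and P2rx7, also ATP-gated channels, rose by 1.18 and 1.17 on the log2 scale, but P2rx4 turned to −0.80 and P2rx7 to 0.05 after median-of-ratios rescaling and to −0.20 and −0.18 after quantile normalisation. P2ry2, a receptor for ATP and UTP, was 5.01 ± 1.66 against 3.76 ± 1.22 TPM (log2 0.32, adjusted p = 0.202) and turned to −1.32 and −1.33 under the same 2 scalings. As a list the receptors did not stand apart from other genes (camera adjusted p = 0.783). The list of danger-signal receptors also holds Hmgb1, itself a signal, and in its full form shares 5 members with the purinergic list. Of its 13 tested genes 12 rose, among them Tmem173 (STING), Tlr4 and Tlr3, with camera adjusted p = 0.156 for the list. After median-of-ratios rescaling 7 rose and 1 fell (adjusted p = 0.0286, while unscaled TPM gave adjusted p = 0.602 with an estimated correlation).

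Matrix and stellate cell genes were the most strongly concentrated groups. All 25 extracellular matrix genes rose, with Dcn (decorin) at 22578 ± 1603 against 37.5 ± 14.9 TPM, Bgn (biglycan) at 9339 ± 694 against 17.2 ± 6.46 TPM, and the collagen gene Col1a1 at 175 ± 39.4 against 0.721 ± 0.113 TPM (camera adjusted p = 0.000181). All 20 genes tied to stellate cell quiescence rose, among them Colec11 (a collectin), Rgs5 (a pericyte gene) and Reln (reelin, an extracellular glycoprotein), with camera adjusted p = 0.000518. All 15 stellate cell markers rose as well (adjusted p = 0.00172), and 10 of these 15 are also on the quiescence list. Hgf, the hepatocyte growth factor, was 1168 ± 204 against 0.569 ± 0.310 TPM, and 16 of 19 growth factor receptors and ligands rose while 1 fell (adjusted p = 0.0316). Further lists with a call were the contractile genes (15 of 15 rose, adjusted p = 0.00731), YAP targets (13 of 14, adjusted p = 0.0214) and TGF-beta responses (15 of 17, adjusted p = 0.0428). Acta2, alpha smooth muscle actin, was 12.0 ± 7.10 against 1.48 ± 0.516 TPM (log2 2.26), and its log2 fold change of 0.74 after median-of-ratios rescaling missed the minimum. With an estimated correlation each of these lists lost its call (adjusted p = 0.602 with an estimated correlation).

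Early-response and inflammatory transcripts were abundant in the freshly isolated cells. Fosb, an AP-1 subunit, was 3282 ± 474 against 0.979 ± 0.632 TPM (log2 10.74), the largest rise, and Fos 7229.7 ± 474 against 29.9 ± 8.92 TPM. All 21 ERK-induced early and feedback genes rose (camera adjusted p = 0.00193). The chemokine gene Ccl2 was 529 ± 32.2 against 0.463 ± 0.320 TPM, and 14 of 15 chemokine and NF-kB response genes rose (adjusted p = 0.0133). Of 18 interferon response genes 17 rose, for example Ifit3 at 354 ± 64.2 against 4.80 ± 0.803 TPM (adjusted p = 0.0133). For these 3 lists the call was also lost (adjusted p = 0.602 with an estimated correlation). Hspa1a, a heat shock protein, was 1495 ± 1062 against 0.436 ± 0.0883 TPM, with 538 to 3009 TPM among the 4 quiescent libraries and 19.0% of its exon bases in another gene model. Of 24 cell division genes 23 rose, with Cdk1, a mitotic kinase, at 38.0 ± 4.93 against 0.866 ± 0.336 TPM (adjusted p = 0.0806, and after median-of-ratios rescaling 15 rose and 1 fell with adjusted p = 0.00517, while unscaled TPM gave adjusted p = 0.751 with an estimated correlation).

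Metabolic lists went the other way or were mixed. Cholesterol synthesis genes fell in 17 of 18 cases, such as Fdft1, squalene synthase, at 1.71 ± 0.239 against 62.3 ± 11.2 TPM with 18.3% of exon bases overlapping (camera adjusted p = 2.19e-18, and adjusted p = 0.144 with an estimated correlation). All 16 hepatocyte markers fell (adjusted p = 3.43e-23, and adjusted p = 0.144 with an estimated correlation), as did all 5 erythroid markers (adjusted p = 1.17e-06, and adjusted p = 0.354 with an estimated correlation). Of 20 genes for UDP-sugar metabolism and transport 8 rose and 6 fell, and after median-of-ratios rescaling 2 rose and 12 fell. Gys2, liver glycogen synthase, was 0.0177 ± 0.0353 against 62.1 ± 16.3 TPM, while Uggt2, a glucosyltransferase of glycoprotein folding, rose by 2.71 on the log2 scale. This list was lower than other genes by camera (adjusted p = 0.00458, and adjusted p = 0.602 with an estimated correlation). Its median was 0.04 and its mean −0.04, and fry's direction was up (adjusted p = 0.249). Retinoid handling (8 of 15 rose, 1 fell, adjusted p = 0.931, and 6 rose and 7 fell after rescaling) held Rbp4, the plasma retinol carrier, at 0.489 ± 0.346 against 3080.2 ± 529 TPM. Glycolysis genes (8 of 18 rose and 4 fell, 5 and 10 after rescaling, median 0.75 with camera's direction down, adjusted p = 0.115) and ER stress genes (13 of 16 rose and 2 fell, 5 and 3 after rescaling, adjusted p = 0.655) gave no call.

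Markers of neighbouring sinusoidal cells were also measured in the sorted cells. Of 15 sinusoidal endothelial markers 14 rose, among them Clec4g, a lectin, at 181 ± 79.2 against 14.8 ± 7.42 TPM (list adjusted p = 0.318, and after median-of-ratios rescaling 9 rose and 1 fell with adjusted p = 0.0414, while unscaled TPM gave adjusted p = 0.863 with an estimated correlation). Of 14 Kupffer cell and macrophage markers 8 rose and 0 fell (adjusted p = 0.931), while after median-of-ratios rescaling 2 rose and 4 fell, and the Kupffer cell lectin Clec4f was 32.9 ± 10.2 against 20.4 ± 6.62 TPM (log2 0.65, below the minimum, and −1.29 after median-of-ratios rescaling). All 14 Kupffer and all 15 endothelial markers reached 1 TPM in quiescent cells. Of 6 portal fibroblast markers 5 rose, or 2 after rescaling (adjusted p = 0.655). Across all genes, 9847 of 12643 tested were called, 8466 higher and 1381 lower in stellate cells (86.0% higher). Groups did not overlap for 11518 genes (91.1%, against 5.71% by chance). The median log2 fold change of all genes was 1.62, and relative to it the medians were 5.49 for matrix, 6.35 for quiescence, 3.12 for ERK-induced, 0.26 for purinergic and −1.58 for UDP-sugar genes. After median-of-ratios rescaling that median was −0.03 and 6715 genes were called, 3250 higher and 3465 lower (48.4% higher), and after quantile normalisation 6490 were called (54.7% higher). Near-identical Mup copies made up 7 of the 10 largest falls, and values of single Mup genes are uncertain.

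The single-cell library was used to see which liver cells carried P2ry14. P2ry14 UMIs were found in 66 of 359 stellate-like cells (18.4%, 95% interval 14.5% to 22.8%) and in 37 of 74 plasmacytoid dendritic cell-like cells, the interferon-producing dendritic cells (50%, 38.1% to 61.9%). They were found in 14 of 423 Kupffer-like cells (3.31%, 1.82% to 5.49%) and in 6 of 2188 sinusoidal endothelial-like cells (0.274%, 0.101% to 0.596%). Summed over cells, P2ry14 was 75.1 CPM (UMIs of the gene relative to all UMIs of the class) in stellate-like cells (60.3 to 92.4), 201 in plasmacytoid dendritic cell-like cells (151 to 263) and 1.45 in endothelial-like cells. No T cell-like (0 of 359, which allows up to 0.836% of cells with a UMI, as 3 cells of the total), B cell-like (0 of 239, up to 1.26%) or plasma cell-like cell (0 of 16, up to 18.8%) carried a P2ry14 UMI. Median UMIs per cell were 3111 in stellate-like, 3412 in plasmacytoid dendritic cell-like, 1999 in Kupffer-like and 1818 in endothelial-like cells. Thinned to 1000 UMIs per cell, the shares were 7.003% (4.58% to 10.2%), 12.2% (5.71% to 21.8%), 1.69% (0.684% to 3.46%) and 0.232% (0.0753% to 0.540%). The thinned intervals of stellate-like and plasmacytoid dendritic cell-like cells overlap, so the thinned shares did not resolve their order. The CPM intervals of these classes did not overlap, with plasmacytoid dendritic cell-like cells higher, and cover counting error only.

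**Figure D2:**
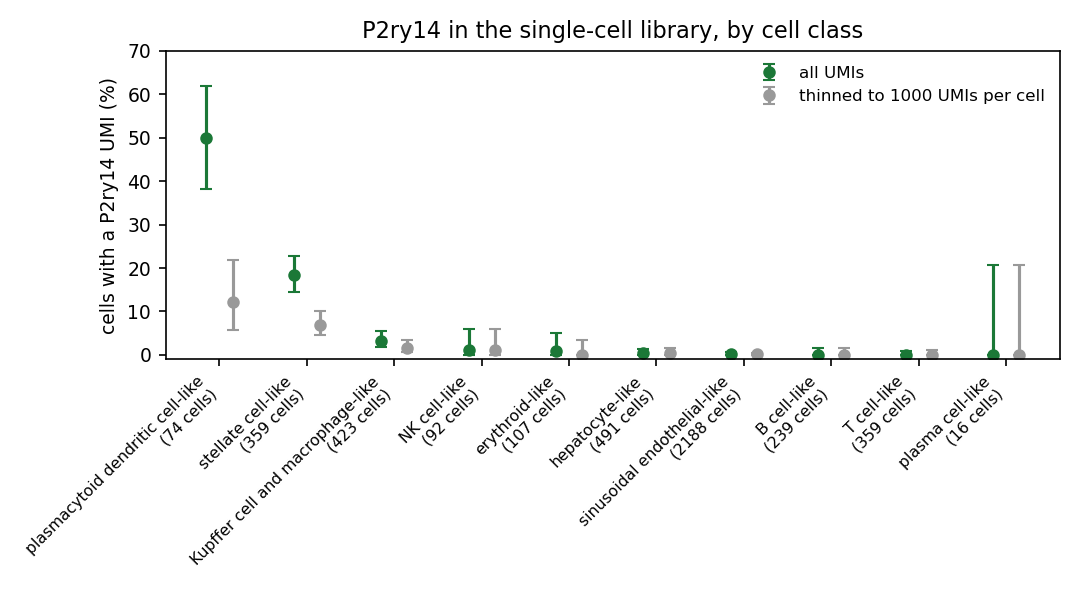
Percentage of cells with a P2ry14 UMI (vertical axis) in each named cell class of the single-cell library, with all UMIs (green) and after thinning each cell to 1000 UMIs (grey). Points are shares and bars are 95% Clopper-Pearson intervals, which cover counting error only. With all UMIs the shares were 50% in plasmacytoid dendritic cell-like and 18.4% in stellate-like cells, against 0.274% in sinusoidal endothelial-like cells.

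The library held 5063 barcodes, 28692 genes and 12101368 UMIs, with a median of 1983 UMIs (968 to 47577) and 1031 genes per barcode. Filters removed 207 barcodes under 200 genes and 63 over 20% mitochondrial UMIs, some of them the same, 4 barcodes scored as doublets were left out, and 4804 cells were kept. Of 21 clusters 17 were named, in 10 classes. Sinusoidal endothelial-like cells were 45.5% of cells (2188), hepatocyte-like 491, Kupffer-like 423, T cell-like 359, stellate-like 359 (7.47%, 6.74% to 8.25%), B cell-like 239, erythroid 107, NK cell-like 92, plasmacytoid dendritic cell-like 74 and plasma cell-like 16. These are shares of the digested cells, not of the intact liver. The 4 unnamed clusters held 456 cells (9.49%). A group of 114 of them led by MHC class II genes and Lyz2 had P2ry14 in 11 cells (9.65%), and a group of 48 that carried both Kupffer (Clec4f, Cd5l) and stellate (Col14a1, Vipr1) genes had it in 6 cells (12.5%). The largest unnamed group, 251 cells led by Fabp4 and Rspo3, had P2ry14 in 0 cells, and a group of 43 led by Hist1h2ap and Spp1 had it in 3 (6.98%). Of all 191 P2ry14 UMIs, 46.6% lay in stellate-like and 28.3% in plasmacytoid dendritic cell-like cells.

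Other purinergic receptors were spread differently. Adora2a was found in 20.3% of stellate-like, 16.3% of NK cell-like, 14.9% of plasmacytoid dendritic cell-like and 13.6% of T cell-like cells (8.68%, 8.89%, 2.70% and 4.49% at 1000 UMIs). P2ry13, P2ry6 and P2ry12 were found in 21.04%, 16.8% and 12.3% of Kupffer-like cells and in 17.6%, 17.6% and 6.76% of plasmacytoid dendritic cell-like cells (12.1%, 7.75% and 5.81% against 0% (0 of 74, up to 4.05%), 5.41% and 1.35% at 1000 UMIs). P2rx4 was found in 25.1% of stellate-like and 24.6% of Kupffer-like cells, and at 1000 UMIs in 7.84% (5.27% to 11.1%) and 12.8% (9.76% to 16.4%). P2rx7 was found in 11.1% of T cell-like, 6.52% of NK cell-like and 5.91% of Kupffer-like cells. At 1000 UMIs these shares were 3.93%, 2.22% and 2.42%, with overlapping intervals. P2ry1 was found in 12.2% of endothelial-like and 9.47% of stellate-like cells (6.63% and 2.24% at 1000 UMIs). Among danger-signal receptors, the formyl peptide receptors Fpr1 and Fpr2 were found in 14.7% and 8.51% of Kupffer-like cells, and Il1r1, the receptor for interleukin-1, in 18.1% of stellate-like cells. Enzymes that make or use UDP-sugars differed in where they were found. Ugp2, which makes UDP-glucose, was found in 39.1% of hepatocyte-like (34.8% to 43.6%) and in 16.4% of stellate-like cells (12.8% to 20.7%), and Ugdh, which oxidises UDP-glucose, in 31.2% and 8.08%. Hepatocyte transcripts were also found in other classes: Alb or Apoa1 in 66.4% of cells, Apoa1 in 30.6% of T cell-like cells, and a median of 3 hepatocyte markers in stellate-like cells. Gys2 was found in 15.9% of hepatocyte-like cells, although their median depth of 1861 UMIs was below that of stellate-like cells.

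UDP-glucose was added to cultured stellate cells to ask how their transcripts respond to a P2Y14 ligand. The sample titles say UDP and the descriptions say UDP-glucose, and the second is used here. Acta2, the usual marker of activated stellate cells, rose from 264 ± 10.1 to 680.3 ± 29.5 TPM (n = 3 per group, log2 fold change 1.36, SE 0.06, limma adjusted p = 0.000154). Ccn2, a secreted matricellular protein, rose from 633 ± 17.4 to 1663 ± 71.4 TPM (log2 1.39, adjusted p = 0.000154), and Tgfb3, a TGF-beta ligand, from 94.4 ± 6.48 to 256 ± 5.26 TPM (log2 1.43, adjusted p = 0.000187). Of the exon bases of Ccn2 and Tgfb3, 23.2% and 12.4% overlap another gene model. Alpl, an alkaline phosphatase, fell from 107 ± 8.42 to 62.4 ± 6.60 TPM (log2 −0.77, not called after median-of-ratios rescaling), and Colec11 from 109.6 ± 6.35 to 68.7 ± 4.12 TPM (log2 −0.67). The collagen gene Col1a1 was 125 ± 4.99 with UDP-glucose and 115 ± 12.7 TPM without (log2 0.12, adjusted p = 0.713). P2ry14 itself was 252, 276 and 269 TPM in treated and 201, 218 and 194 TPM in control libraries (266 ± 12.2 against 204 ± 12.2, log2 0.38, SE 0.07), higher in 3 of 3 libraries but not called (adjusted p = 0.0649).

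**Figure D3:**
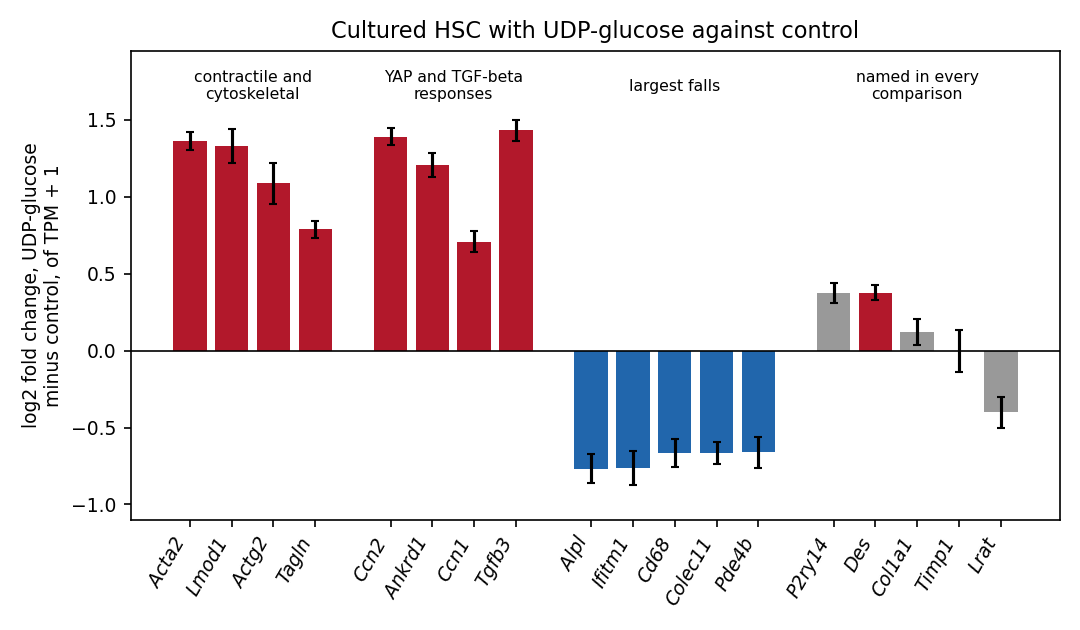
Log2 fold changes of TPM + 1 (vertical axis, UDP-glucose minus control, n = 3 per group) for genes of the contractile list, of the YAP and TGF-beta lists, for 5 of the largest falls outside predicted models and for genes named in every comparison. Bars are fold changes with their standard error, red for genes called higher, blue for genes called lower and grey for genes not called. Acta2, Ccn2 and Tgfb3 lie at 1.36, 1.39 and 1.43, Alpl at −0.77 and Col1a1 at 0.12.

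Of 18 contractile and cytoskeletal genes 8 rose and 0 fell, and 14 rose adjusted over the list alone (camera adjusted p = 3.27e-35, and adjusted p = 0.0128 with an estimated correlation). Besides Acta2 they included Lmod1, an actin filament nucleator of smooth muscle (12.8 ± 1.35 to 33.8 ± 2.97 TPM), Actg2, smooth muscle gamma actin (3.78 ± 0.251 to 9.17 ± 1.01 TPM), and Tagln, an actin-binding protein (1665 ± 4.92 to 2881 ± 150 TPM). Of Tagln's exon bases 67.9% overlap another gene model. Of 7 smooth muscle markers, 5 of which are also on the contractile list in its full form, 4 rose, and 5 adjusted over the list alone (adjusted p = 1.63e-13, and adjusted p = 0.0371 with an estimated correlation). Des rose from 189.5 ± 2.99 to 247 ± 4.38 TPM (adjusted p = 0.0258).

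Of 15 YAP targets 3 rose and 0 fell, with 7 rises adjusted over the list alone (camera adjusted p = 1.63e-13, and adjusted p = 0.179 with an estimated correlation). They were Ccn2, Ankrd1, a muscle ankyrin repeat protein (105 ± 5.05 to 243 ± 21.05 TPM), and Ccn1, a matricellular protein (461 ± 20.6 to 755 ± 51.6 TPM). Of 17 TGF-beta response genes 3 rose and 0 fell, Tgfb3 and Ccn2 among them, with 4 rises and 1 fall adjusted over the list alone. The TGF-beta list was higher by camera (adjusted p = 0.0314, and adjusted p = 0.431 with an estimated correlation), although its median log2 fold change was −0.05 and its mean 0.18. Further rises included Lmcd1, a LIM domain protein (6.47 ± 0.967 to 17.8 ± 0.306 TPM), Bdnf, a neurotrophin (3.33 ± 0.349 to 8.54 ± 1.11 TPM, 14.4% of exon bases overlapping), and Vgll3, a TEAD cofactor (2.75 ± 0.320 to 6.92 ± 0.880 TPM).

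Of 20 quiescence genes Colec11 fell, and adjusted over the list alone 7 fell and 1 rose (camera adjusted p = 0.00012, and adjusted p = 0.334 with an estimated correlation). Lrat was 65.4 ± 3.06 against 87.2 ± 11.2 TPM (log2 −0.40, adjusted p = 0.203). Of 15 stellate cell markers Des rose and Colec11 fell, and adjusted over the list alone 2 rose and 6 fell (adjusted p = 0.00642, and adjusted p = 0.455 with an estimated correlation). Of 18 growth factor receptors and ligands Agtr1a, the angiotensin receptor, fell from 232 ± 11.2 to 178 ± 5.46 TPM (not called after median-of-ratios rescaling), with 4 falls adjusted over the list alone (adjusted p = 0.00642, and adjusted p = 0.493 with an estimated correlation). Ifitm1, an interferon-induced membrane protein, fell from 154 ± 22.4 to 89.4 ± 5.02 TPM (not called after rescaling). None of the 17 tested interferon response genes passed, with 1 fall adjusted over the list alone, while the list lay lower by camera (adjusted p = 2.73e-05, and adjusted p = 0.417 with an estimated correlation). Chemokine and NF-kB response genes gave 0 of 14 calls, with 2 falls adjusted over the list alone (adjusted p = 0.0402, and adjusted p = 0.493 with an estimated correlation). Cd68, a lysosomal protein of macrophages that is also found in other cells, fell from 77.6 ± 8.20 to 48.4 ± 2.71 TPM (not called after rescaling). Of 14 Kupffer and macrophage markers 2 reached 1 TPM in these cultures, and the Kupffer lectin Clec4f was listed at 0 in all 3 controls.

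Other lists held no called gene. ERK-induced genes gave 0 of 20 calls, or 3 rises adjusted over the list alone (camera adjusted p = 0.00012, and adjusted p = 0.330 with an estimated correlation), and cholesterol synthesis 0 of 17 (adjusted p = 0.0157, and adjusted p = 0.493 with an estimated correlation). Extracellular matrix genes gave 0 of 25 calls, or 2 rises and 1 fall adjusted over the list alone (adjusted p = 0.373, median −0.05, camera's direction up), and Timp1, an inhibitor of matrix proteases, was 17.8 ± 0.390 against 18.0 ± 3.26 TPM. Calls were also 0 for purinergic receptors (9 tested, adjusted p = 0.826), danger-signal receptors (14, adjusted p = 0.542), UDP-sugar genes (19, adjusted p = 0.819), retinoid handling (14, adjusted p = 0.373), cell division (18, adjusted p = 0.373), glycolysis (16, adjusted p = 0.834) and ER stress (17, adjusted p = 0.170). Adjusted over the list alone, 1 purinergic and 1 danger-signal receptor rose, in both cases P2ry14. The medians of these 2 receptor lists were −0.03 and −0.04 and their means −0.06 and −0.05, while camera's direction was up. The receptor P2rx7 was 15.9 ± 1.80 against 22.5 ± 5.65 TPM (log2 −0.45, adjusted p = 0.443). Hepatocyte (5 tested), endothelial (5) and portal fibroblast markers (6) gave 0 calls, with adjusted p = 0.373, 0.124 and 0.195, and 2 endothelial markers fell adjusted over the list alone. The hepatocyte median was −0.06, its mean 0.58 and camera's direction up.

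In total 74 of 12161 genes were called, 52 higher and 22 lower (70.3% higher), and 1220 had an unadjusted p under 0.05. The groups did not overlap for 1979 genes (16.3%, against 10% by chance). Leaving out UDP-glucose replicate 1, 2 or 3 gave 30, 20 and 24 calls and leaving out control replicate 1 or 3 gave 24 and 21, and 8 of the 24 called genes that the naming rule took were called in all 6 fits that left out a library, among them Tgfb3, Ccn2, Acta2 and Lmod1. Lmcd1 was called in 5 of these fits, Alpl in 2, Actg2, Bdnf, Colec11, Cd68 and Ifitm1 in 1, and Vgll3, Des, Agtr1a and Pde4b in 0. Median-of-ratios rescaling called 66 genes higher and 12 lower (84.6% higher) and brought P2ry14 to a log2 fold change of 0.43 with adjusted p = 0.0338, the lowest in a range of 0.0338 to 0.346 over its alternatives.

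Control cultures were compared with quiescent cells to describe the untreated state of the cultures. Acta2 was 264 ± 10.1 TPM in cultured (n = 3) and 12.0 ± 7.10 TPM in quiescent cells (n = 4, log2 fold change 4.50, limma adjusted p = 3.43e-06), and Lrat fell from 1089 ± 205 to 87.2 ± 11.2 TPM (log2 −3.62, adjusted p = 1.16e-07). Fos fell from 7229.7 ± 474 to 9.98 ± 1.26 TPM (log2 −9.37) and Fosb from 3282 ± 474 to 1.03 ± 0.163 TPM (log2 −10.65), the largest fall. Asns, asparagine synthetase, rose from 0.461 ± 0.212 to 154 ± 7.497 TPM (log2 6.74). P2ry14 was 204 ± 12.2 against 132 ± 4.78 TPM (log2 0.63, SE 0.06, adjusted p = 2.30e-05), below the fold minimum. Col1a1 was 115 ± 12.7 against 175 ± 39.4 TPM (log2 −0.57, below the minimum). Cultured cells differ from quiescent cells in culture, strain, sorting and table at once, and these cannot be told apart.

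**Figure D4:**
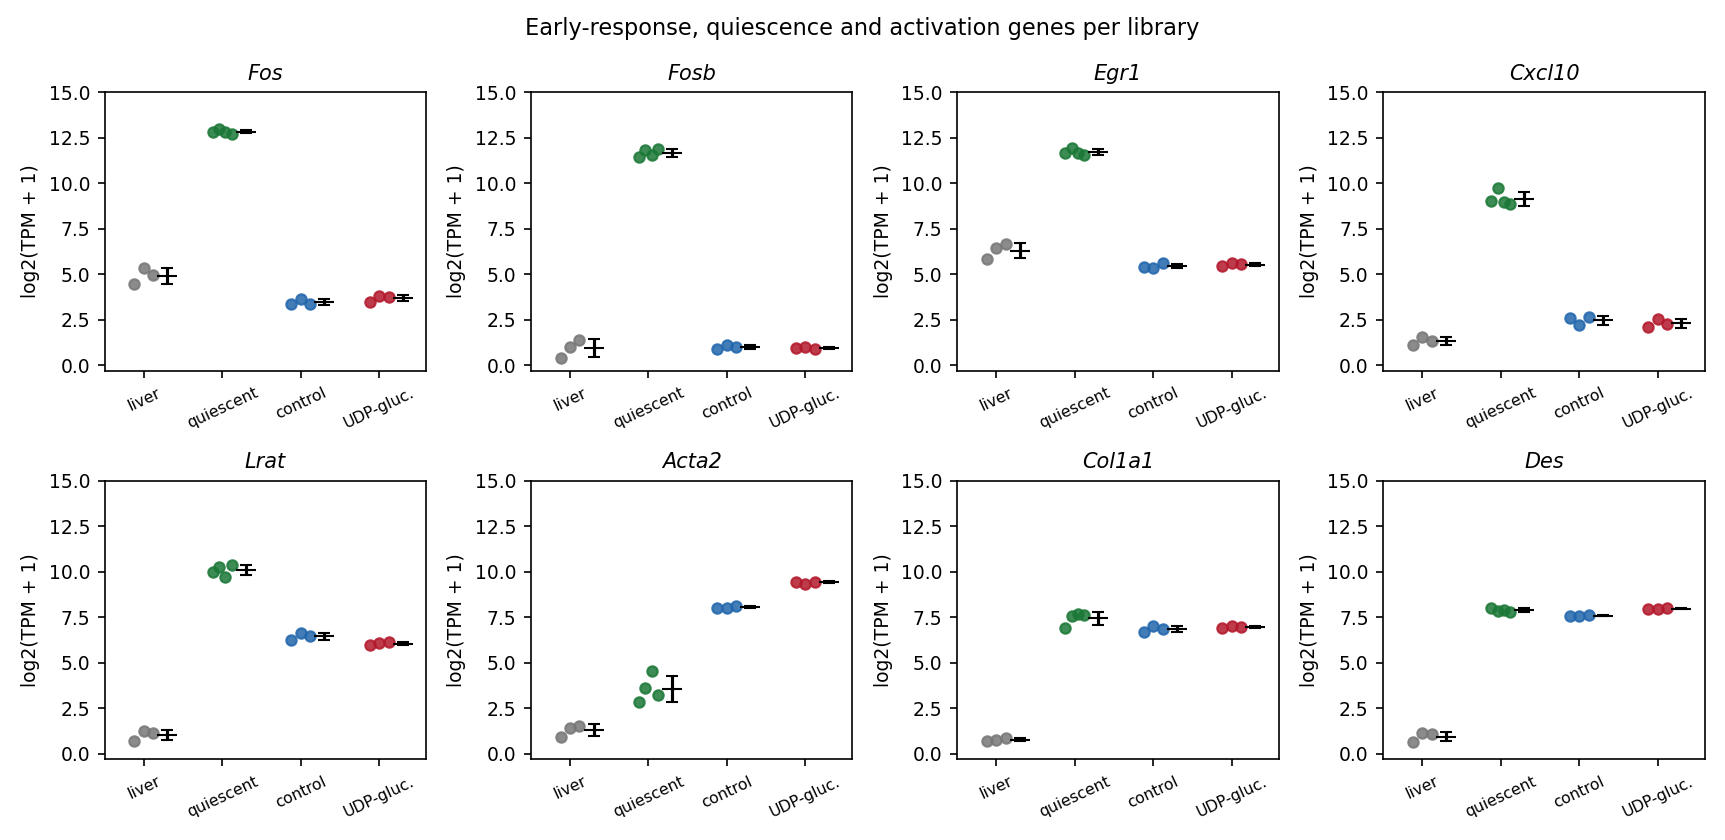
Log2(TPM + 1) (vertical axis) of 8 genes in the 13 bulk libraries, by group: early-response genes Fos, Fosb and Egr1, the chemokine gene Cxcl10, Lrat, Acta2, Col1a1 and Des. Dots are libraries and bars are the mean ± SD of the log2 values. Fos had a mean of 7229.7 TPM in quiescent cells and 9.98 TPM in control cultures, and Acta2 264 TPM in control and 680.3 TPM in UDP-glucose cultures.

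Of 20 quiescence genes 19 fell (camera adjusted p = 8.33e-15, and adjusted p = 0.00685 with an estimated correlation), led by Ngfr, a neurotrophin receptor (315 ± 39.4 to 4.57 ± 0.951 TPM), and Colec11 (4963 ± 255 to 109.6 ± 6.35 TPM). Of 15 stellate cell markers 13 fell (adjusted p = 6.53e-11, and adjusted p = 0.00976 with an estimated correlation). Of 17 contractile genes 12 rose, among them Tagln (290 ± 39.3 to 1665 ± 4.92 TPM) and Lmod1 (log2 2.81), with adjusted p = 0.00103, and adjusted p = 0.178 with an estimated correlation. Matrix genes fell in 14 of 25 cases, such as Col1a2, a type I collagen chain (572 ± 41.2 to 70.9 ± 10.3 TPM), with adjusted p = 4.94e-08, and adjusted p = 0.150 with an estimated correlation. Of 17 TGF-beta response genes 4 rose and 4 fell (adjusted p = 0.0109, and adjusted p = 0.150 with an estimated correlation). Tgfb3 rose from 16.0 ± 1.92 to 94.4 ± 6.48 TPM and Tgfbi, a secreted matrix protein, fell from 4425 ± 451 to 143 ± 7.95 TPM. YAP targets were mixed (2 rose and 3 fell of 15, 2 and 5 after median-of-ratios rescaling, adjusted p = 0.325, with a median of 0.03, a mean of 0.21 and camera's direction down). Ankrd1 rose from 0.315 ± 0.223 to 105 ± 5.05 TPM, while Ccn1 fell from 2522 ± 565 to 461 ± 20.6 TPM. Growth factor receptors and ligands fell in 10 of 19 cases with 1 rise (adjusted p = 3.45e-06, and adjusted p = 0.194 with an estimated correlation), Hgf among them (1168 ± 204 to 184 ± 48.4 TPM).

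Early-response and immune transcripts were lower in culture. Of 21 ERK-induced genes 16 fell and 1 rose (camera adjusted p = 5.72e-11, and adjusted p = 0.150 with an estimated correlation), Egr1, a zinc finger transcription factor, from 3348 ± 349 to 42.7 ± 3.94 TPM. Chemokine and NF-kB genes fell in 10 of 17 cases with 1 rise (adjusted p = 8.94e-06, and adjusted p = 0.163 with an estimated correlation), Cxcl10 from 578 ± 179 to 4.60 ± 0.901 TPM. Interferon response genes fell in 13 of 18 cases (adjusted p = 7.02e-07, and adjusted p = 0.222 with an estimated correlation). Cell division genes fell in 12 of 24 cases with 1 rise (adjusted p = 0.000341, and adjusted p = 0.331 with an estimated correlation), Top2a, topoisomerase II alpha, from 17.4 ± 5.07 to 1.19 ± 0.413 TPM. Of 15 endothelial markers 14 fell, Clec4g from 181 ± 79.2 to 0.266 ± 0.152 TPM (adjusted p = 1.31e-08, and adjusted p = 0.222 with an estimated correlation). Of 14 Kupffer and macrophage markers 12 fell and 1 rose (adjusted p = 9.73e-07, and adjusted p = 0.222 with an estimated correlation). Clec4f was listed at 0 in all 3 cultured libraries against 32.9 ± 10.2 TPM. Cd68 rose from 35.3 ± 9.22 to 77.6 ± 8.20 TPM (log2 1.14, and 0.87 after median-of-ratios rescaling, below the minimum). Portal fibroblast markers fell in 4 of 7 cases with 1 rise (adjusted p = 0.0430, and adjusted p = 0.331 with an estimated correlation). The 3 tested erythroid markers rose, among them the haemoglobin gene Hba-a1 from 0.529 ± 1.06 to 5.12 ± 0.0805 TPM, too few for a list test.

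Metabolic lists differed from each other in culture. Cholesterol synthesis genes rose in 13 of 17 cases (camera adjusted p = 0.000272, and adjusted p = 0.185 with an estimated correlation), such as Fdft1 (1.71 ± 0.239 to 18.0 ± 0.693 TPM). Of 19 UDP-sugar genes 6 rose and 0 fell, Ugdh from 29.6 ± 2.39 to 98.8 ± 3.44 TPM (adjusted p = 0.0979). Glycolysis genes rose in 7 of 17 cases with 1 fall (adjusted p = 0.0696). Of 17 ER stress and amino acid response genes 5 rose and 1 fell (adjusted p = 0.381), with Trib3, a stress-induced pseudokinase, at 73.4 ± 0.586 against 0.144 ± 0.134 TPM. Retinoid handling fell in 7 of 14 cases with 2 rises, or 8 and 0 after median-of-ratios rescaling (adjusted p = 0.0109, and adjusted p = 0.178 with an estimated correlation). Among 7 purinergic receptors P2rx7 (2.75 ± 1.03 to 22.5 ± 5.65 TPM) and P2ry2 (5.01 ± 1.66 to 21.1 ± 0.758 TPM) rose, and P2ry1, P2rx1 and Adora2a fell by 2.34, 2.51 and 2.56 on the log2 scale (list adjusted p = 0.591). The purinergic median was 0.63 and its mean −0.20. Danger-signal receptors (3 rose and 3 fell of 14, 2 and 5 after rescaling, median −0.05, mean 0.00, adjusted p = 0.325), hepatocyte markers (1 rose and 3 fell of 7, adjusted p = 0.297) and smooth muscle markers (4 rose and 1 fell of 6, adjusted p = 0.387) gave no call. Counts adjusted over the list alone equalled those over all genes for every list in this comparison and in that with liver.

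In total 3990 of 12537 genes were called, 2338 higher and 1652 lower in culture (58.6% higher), and the groups did not overlap for 8770 genes (69.95%, against 5.71% by chance). The median log2 fold change of all genes was 0.26, and relative to it the medians were −3.52 for quiescence, −2.35 for ERK-induced, −1.63 for matrix, 1.05 for contractile and 1.41 for cholesterol synthesis genes. After median-of-ratios rescaling the median of all genes was 0.00 and 1514 genes were called higher and 2061 lower (42.3% higher). Outside predicted models and pseudogenes, several of the largest rises belong to families with near-identical copies, H2-Q2, Hmga1b, Tpm3-rs7 and Ifi202b among them, and their values are uncertain.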

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

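The tests on free RNA in the droplets, on Dcn UMIs and on other splits of the libraries were chosen only after the results they measure were seen.

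In the 4 quiescent stellate cell libraries, 20 of 167 named genes (12.0%) had a library far from the other 3, by the gap to its nearest neighbour relative to the range. Chance gives about 1 in 20 for normally spread values, and 0 of 5 library measures stood out. For Adora1, Gys2, Hba-a1, H2-Q2 and Cyp1a1 the other 3 libraries were listed at 0, so any value above 0 was bound to stand far. The 12.0% includes these genes and cannot be set directly against 1 in 20. Among genes of stellate cells and matrix, Postn, a matricellular protein, was 2235 TPM in replicate 1 (others 929.8 to 1152), Rgs5 3768 TPM in replicate 4 (others 2474 to 2679.7), Hgf 866 TPM in replicate 3 (others 1226 to 1296) and Tgfbi 3749 TPM in replicate 3 (others 4627 to 4679). Pmepa1, a TGF-beta feedback gene, was 104 TPM in replicate 3, Tgfb3 18.8 TPM in replicate 2 and Tpm1, a tropomyosin, 262 TPM in replicate 2. The chemokine genes Cxcl10 and Ccl2 were 844 and 577 TPM in replicate 2 (others 453 to 515 and 508 to 519). Vegfa, an endothelial growth factor, was 12.5 TPM and Tlr3 16.1 TPM in replicate 3, and Slc2a1, a glucose transporter, 43.9 TPM in replicate 4. Tpm3-rs7, a tropomyosin copy, was 66.1 TPM in replicate 4 and 0.274 to 0.553 TPM in the others. At low levels, single libraries were highest for Hba-a2 (5.05 TPM) and Hba-a1 (2.12 TPM), both haemoglobin chains, in replicate 2, Ighm, an immunoglobulin chain, in replicate 3 (1.76 TPM), Cyp1a1 (0.108 TPM) and Gys2 (0.0706 TPM) in replicate 2, and H2-Q2 (0.0970 TPM) and Adora1 (0.0307 TPM) in replicate 4. Of the 20 values 8 lay in replicate 2, 6 in replicate 3, 5 in replicate 4 and 1 in replicate 1.

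Entries named as calendar dates, which no comparison used, held up to 0.319% of TPM in a quiescent library. They held 0.301% ± 0.0140 in quiescent cells (n = 4), 0.0823% ± 0.0135 in liver (n = 3), 0.144% ± 0.00831 in control cultures (n = 3) and 0.142% ± 0.00712 in UDP-glucose cultures (n = 3). Their genes could not be told from the names.

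P2ry14 UMIs were found outside stellate-like cells, in 37 of 74 plasmacytoid dendritic cell-like and 14 of 423 Kupffer-like cells. Free RNA from broken cells should reach all droplets alike. At 1000 UMIs per cell P2ry14 was found in 12.2% of plasmacytoid dendritic cell-like (5.71% to 21.8%, median depth 3412 UMIs before thinning) and 1.69% of Kupffer-like cells (0.684% to 3.46%, depth 1999). Sinusoidal endothelial-like cells had 0.232% (0.0753% to 0.540%, depth 1818), which argues against free RNA as the whole source in both classes. Droplets that also held a stellate cell would carry its abundant transcripts. In Kupffer-like cells with P2ry14, stellate markers stood at 1.75% of their level in stellate-like cells (1.05% to 2.73%). A cluster of 48 cells with both Kupffer and stellate genes, 6 of them with P2ry14, had been left unnamed. Cells with both sets of genes were thus set apart beforehand, so the low level in Kupffer-like cells cannot decide on shared droplets. In plasmacytoid dendritic cell-like cells with P2ry14 stellate markers stood at 4.45% (3.84% to 5.14%), far under the 25% set for such droplets. The upper bound narrowly missed the 5% set as the limit against them. The level was 2.24% in those without P2ry14, so a small contribution of stellate transcripts stays open. Dcn was found in 43.2% of plasmacytoid dendritic cell-like cells with P2ry14 (27.1% to 60.5%) and in 98.1% of stellate-like cells (96.0% to 99.2%), which argues against shared droplets as the whole source. A candidate explanation is that these cells transcribe P2ry14 themselves, a hypothesis from the data it was tested on. Scrublet called 4 barcodes and gives no help here.

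Early-response genes stood high in quiescent cells. The sum of Fos, Fosb, Egr1, Jun, Junb and Ier2 was 21911 ± 1535 TPM in quiescent cells (n = 4), 333 ± 85.2 TPM in liver (n = 3), 324 ± 10.96 TPM in control cultures (n = 3) and 337 ± 4.37 TPM in UDP-glucose cultures (n = 3). Scaling of TPM by abundant hepatocyte transcripts was argued against as the whole cause. With median-of-ratios rescaling the median log2 difference from liver of the 21 called early-response genes went from 4.75 to 3.08 (0.94 to 9.26, highest standard error 0.25), while the median of all genes went from 1.62 to −0.03. Isolation of the cells from the tissue may have induced these genes. In the digested liver 2 named classes reached at least 0.5 of the stellate-like level of 1483 CPM: Kupffer-like cells at 79.3% and hepatocyte-like cells at 50.9%. Endothelial-like cells stood at 42.8%, B cell-like at 33.8%, T cell-like at 33.2%, plasmacytoid dendritic cell-like at 20.6% and erythroid cells at 4.14%. The 456 cells of unnamed clusters, which do not count as a named class, stood at 93.3% (89.1% to 97.7%). The 2 named classes are fewer than the 5 set for this explanation and more than its absence allowed. Isolation and the state of the cells in the liver therefore cannot be told apart.

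Outside predicted models and pseudogenes, copies of gene families stood at the head of the cultured against quiescent list: Hmga1b (101 TPM against listed at 0), H2-Q2, Tpm3-rs7 and Ifi202b (51.7 TPM against listed at 0). Reads moved between copies by strain variants are a candidate explanation, since the cultured cells are labelled Balbc and the quiescent cells C57BL/6J. Of 351 pairs of a pseudogene and its parent, 15 had a moved ratio, and 4 of these (26.7%, 7.79% to 55.1%) kept their summed level. Among these was Rpl3, a ribosomal protein, at 131 against 672 TPM with Rpl3-ps1 at 845 against 0.357 TPM. The share that kept its sum is not a clean measure of moved reads. The pseudogenes Esd-ps, Prdx6-ps2 and Rps18-ps2 were listed at 0 in both groups, so their ratio moved with the parent alone and their sum could not be kept. The parents Rps18 and Rpl34 also entered more than once, so the pairs are not independent. Between quiescent cells and liver, labelled with the same strain, 4 of 265 pairs moved and 0 kept their sum. Of these pseudogenes, Aldoa-ps3 and Ptma-ps1 were listed at 0 in both groups and Ly6e-ps1 at 0.109 and 0 TPM. Their ratio moved with the parent, so the count of 0 is of little use as a contrast. With these pairs, moved reads and changed transcription cannot be told apart for the families above.

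Of the 10 splits of the 6 cultured libraries, 1, the real one, gave as many called genes for UDP-glucose (74, highest other 2), and 10 splits are too few for a share under 0.05. Every other split also mixes treated and control libraries within a group. This widens the spread of genes that respond, so 74 against 2 is not a fair measure of chance. For quiescent cells against liver 1 of 35 splits, the real one, gave as many (9847, highest other 4), and for cultured against quiescent cells 1 of 35 (3990, highest other 3). In these 2 comparisons every other split mixes unlike samples within a group, which widens the spread and keeps the calls few. The splits therefore cannot measure chance for these 2 counts, and differences between tables are not excluded either.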

How the results depend on the processing

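Leaving out the cells of unnamed clusters was chosen only after the results were seen. With UDP-glucose, of 971 values of 66 named genes under the alternatives 843 kept their side of the threshold and 0 reversed. Most of these genes had no call to lose, and all 127 values that lost a call belong to the 24 called genes. When a library was left out, 76 of 393 values lost a call. The 74 calls became 30 with no filter on low values, 25 without a variance trend and 23 with all 13 libraries in 1 fit. They became 30, 20 and 24 without UDP-glucose replicate 1, 2 or 3 and 24, 64 and 21 without control replicate 1, 2 or 3, with fewer libraries in each fit. P2ry14 passed at a log2 fold change of 0.43 with median-of-ratios rescaling (range of adjusted p 0.0338 to 0.346). Lists called went from 11 to 2 with an estimated correlation and 6 with fry.

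For quiescent cells against liver, 2053 of 2088 values of 117 named genes kept their side. Calls went from 9847 to 6490 with quantile normalisation. P2ry14 was called under all 18 alternatives (log2 5.41 to 8.30). Values reversed for P2ry2 (0.32 to −1.32 with median-of-ratios and −1.33 with quantile scaling), P2rx4 (1.18 to −0.80 and −0.20), P2rx7 (1.17 to −0.18 with quantile scaling) and Clec4f (0.65 to −1.29 with median-of-ratios). With quantile scaling Batf3 went from 1.15 to −0.12, Dpt from 1.57 to −0.0863 and Entpd2 from 1.61 to −0.0146. Lists called went from 14 to 0 with an estimated correlation, 22 with fry and 22 with no filter. Fry turned the direction of UDP-sugar genes (adjusted p = 0.249) and glycolysis genes (adjusted p = 6.68e-06) to up.

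For cultured against quiescent cells, 1971 of 1999 values of 112 named genes kept their side. Without a fold minimum calls went from 3990 to 8924 and P2ry14 was called at 0.63, by construction. Lists called went from 15 to 2 with an estimated correlation.

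The stellate-like share of cells went from 7.47% to 8.45% at resolution 0.5, 8.26% without unnamed clusters and 0.0624% (3 cells) with classes set from detected markers. The share with P2ry14 was 7.003% at 1000 UMIs per cell, where depth limits it, and 0% (0 of 3) with classes from markers. Of 356 stellate-like cells with 3 or more stellate markers, 293 also held 2 or more hepatocyte markers, over the 1 marker of another type that this setting allows. For the other changes above the cause was not tested. No paired analysis was possible because the labels give no numbers shared between groups.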

Other observations

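No test was run for this part, and the genes named here were chosen after their values were seen.

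UMIs of UDP-sugar enzymes, Ugcg and Galk1 among them, were also found outside hepatocyte-like cells. In the same library Apoa1, a hepatocyte transcript, was found in 30.6% of T cell-like cells. Ugcg, which joins glucose from UDP-glucose to ceramide, was found in 30.4% of 92 NK cell-like cells (21.3% to 40.9%) and 18.4% of 359 T cell-like cells (14.5% to 22.8%), or 16.7% and 6.18% at 1000 UMIs. Galk1, galactokinase, was found in 23.0% of 74 plasmacytoid dendritic cell-like (13.99% to 34.2%), 14.1% of 491 hepatocyte-like and 13.9% of 359 stellate-like cells. At 1000 UMIs per cell the shares were 5.41%, 5.07% and 5.602%. Gbe1, the glycogen branching enzyme, Entpd5, which hydrolyses UDP in the secretory pathway, and Slc35d1, a UDP-sugar transporter, were found in 17.3%, 16.1% and 15.7% of hepatocyte-like cells, or 6.98%, 6.55% and 4.65% at 1000 UMIs. Median depths were 1906 UMIs in NK cell-like, 2477 in T cell-like, 3412 in plasmacytoid dendritic cell-like, 1861 in hepatocyte-like and 3111 in stellate-like cells.

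Hmgb1, a nuclear protein released by dying cells, was found in 83.6% of stellate-like (79.3% to 87.2%), 82.4% of plasmacytoid dendritic cell-like, 64.8% of endothelial-like, 57.4% of hepatocyte-like and 42.6% of Kupffer-like cells. At 1000 UMIs per cell the shares were 50.4%, 32.4%, 44.2%, 32.8% and 22.5%. Tmem173 was found in 17.6% of plasmacytoid dendritic cell-like and 9.22% of Kupffer-like cells, and Tlr4 in 9.93% of Kupffer-like cells, or 6.76%, 4.12% and 5.08% at 1000 UMIs.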
